A study of Mus musculus with 12 samples.

How the data were processed

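RNA-seq was carried out on 12 libraries of mouse osteoclasts, the bone-resorbing cells that form when monocytes are cultured with M-CSF and RANKL. Per the labels' protocols, bone marrow monocytes of mice aged 8 to 12 weeks were cultured for 4 days, total RNA was prepared with a Quick RNA Microprep kit, and libraries were made with the NEBNext Ultra II kit. The labels give 4 groups of 3 libraries: male control, male Per1 knockout, female control and female Per1 knockout. Each library also has a biological replicate number from 1 to 3 and a batch of the same number. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples, which may be technical in part.

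The deposited table holds FPKM (fragments per kilobase of gene length, scaled by library depth) for 55806 genes, with gene identifiers, symbols, coordinates and lengths. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and build mm10, with no role or parameters, and whether counting used strand is not given in the sources used here. The coordinates in the table were identical to those of GENCODE M21 on GRCm38 for 1457 of 52080 shared gene identifiers (2.80%), so the build behind the printed coordinates is uncertain. FPKM times gene length was a whole multiple of 1 step in 100% of values of each library, within a tolerance of 0.01. Fragments per gene were rebuilt from these steps and summed to between 15366600 and 24346288 per library. At this depth, 3 fragments on a gene of 1 kb correspond to 0.119 to 0.188 FPKM, and this floor covers counting error only. Genes with close copies, such as Pirb, Lilrb4a, H60b, Akr1c13, Oas1a, Oas1g, Ifi27l2a and H2-Aa, are uncertain where counting could split reads between copies. 1 line of the table was emptied for this work and was not used here.

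Genes with FPKM of 1 or more in at least 3 libraries were tested, which kept 12237 genes and removed 43569. Because FPKM are not counts, limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) of all 12 libraries, with a mean for each group, moderated variances with a trend, two-sided tests and Benjamini-Hochberg adjustment at 0.05. Fold changes on this scale understate the change of genes with low FPKM. The contrasts were knockout against control in males, in females and averaged over both sexes, the difference of the knockout effect between the sexes (female minus male), and female against male control. The design, the gene lists, the rule for named genes and most alternative settings were chosen before the data were examined.

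The 25 gene lists covered osteoclast genes, inhibitors of osteoclast formation, clock genes, inflammatory mediators, pattern recognition and NF-kB, type I interferon response, complement, coupling factors made by osteoclasts, markers of 8 sets of bone marrow cell types, and 9 sets of cell state genes. The cell type sets were monocytes and macrophages, MHC class II and dendritic cells, neutrophils, mast cells with basophils and eosinophils, stromal cells, lymphocytes, erythroid cells and endothelium. The cell state sets were cell cycle, immediate early and heat shock, glucocorticoid response, the mitochondrial genome, nuclear oxidative phosphorylation, glycolysis, V-ATPase and lysosome, cholesterol synthesis and ribosomal proteins. Lists were tested with limma's camera at a preset correlation of 0.01, repeated with an estimated correlation and with fry, with adjustment over the 25 lists of a contrast. Members past 0.05 were counted over all genes and adjusted over the list alone.

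Named genes were Per1 and, per direction, up to 10 called protein-coding genes with the largest change whose libraries did not overlap and whose mean reached 2 FPKM in a compared group. Where fewer than 5 qualified in a direction, the 5 such genes of lowest p were taken whether or not they passed. From each list of main interest up to 4 members of lowest p were taken, and up to 2 from the other lists. The 5 genes of lowest p per direction were taken for the difference between the sexes and for the sex comparison, with Xist and 4 Y-linked genes as sex checks.

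Alternatives covered the pseudocount, the filter, 3 ways of rescaling, the variance model, library weights, voom on the rebuilt fragments, the threshold, the libraries in the fit, the replicate number as a block, and leaving out each library in turn. A term for the share of fragments on rRNA genes, a fit of the 8 libraries with the higher share, a fit of the 9 libraries with a low interferon score, and permutations of list scores, freely within sex and only within same-numbered pairs, were added after seeing the data. The labels give same-numbered libraries a shared batch, so the number pairs them by design. Deviations from the group means gave little sign of it: of 18 same-numbered pairs 4 correlated above 0.1, from -0.217 to 0.44, with a mean of -0.00339 against -0.000662 for other pairs. Within each group, rebuilt fragments of every pair of libraries differed by more than counting noise (chi-square per degree of freedom 5.71 to 59.7), so no library was a copy of another of its group. Libraries of different groups were not compared in this way.

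The scripts were tested on simulated libraries with 200 genes changed 1.5-fold, 2-fold or 4-fold. In the male contrast over 12151 genes 44.8%, 70.2% and 87.9% of these were recovered, and in the female contrast over 12133 genes 49.3%, 74.6% and 86.4%. The averaged contrast over 12177 genes recovered 62.7%, 74.6% and 92.4%, the difference between the sexes over 12152 genes 19.4%, 55.2% and 87.9%, and the sex contrast over 12164 genes 49.3%, 74.6% and 92.4%. Unchanged genes called numbered 6, 15, 10, 6 and 7 in these contrasts, and simulations with no change gave 0 calls by limma and 0 by voom in each contrast, with 572 to 667 of 12166 genes at an unadjusted p under 0.05 by limma. A list raised 1.5-fold in the simulated male libraries labelled knockout had an adjusted p of 1.39e-44 by limma's camera and 5.72e-06 with an estimated correlation, and the unchanged lists gave 0 calls in that contrast and in the averaged one. In the female contrast, where no list was raised, camera called 2 lists, and in the difference between the sexes it called 1 unchanged list, against 0 with an estimated correlation in each. Simulated genes were drawn independently of each other, while the estimated correlation in the real libraries was 0.4104 for osteoclast genes and 0.9771 for interferon genes. The simulated list results therefore do not carry over to lists of correlated genes. With independent genes and 200 changed at once, the recovered shares of genes may also overstate recovery in the real libraries. Values were tabulated with pandas 2.3.3 in Python 3.11.15 and drawn with matplotlib 3.10.9.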

Results

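Gene expression was measured by RNA-seq in osteoclasts grown for 4 days from bone marrow monocytes of mice labelled control and mice labelled Per1 knockout, to ask which osteoclast and inflammatory genes differ between these labels. Per1 encodes a repressor of the circadian clock. The 12 libraries formed 4 groups of 3, with cells of male and of female mice kept apart, and values are FPKM with n = 3 per group. Depth was similar between groups, from 15366600 fragments in male knockout 1 to 24346288 in male knockout 2, and 11207 to 12060 genes per library reached 1 FPKM. Mitochondrial genome transcripts took 2.80% to 3.73% of the fragments of a library, and the 20 most abundant genes took 10.7% to 12.9%.

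Per1 (ENSMUSG00000020893, chromosome 11, 68986043 to 69000786 on the plus strand in the deposited table, whose build is uncertain) was expressed in all 12 libraries. In males it averaged 3.34 ± 0.563 FPKM (SD, n = 3) in controls, with 3.70, 3.63 and 2.69 in the individual libraries. The male libraries labelled knockout had 2.36, 2.66 and 2.99 FPKM, a mean of 2.67 ± 0.314 or 79.9% of control (two-sided exact permutation p = 0.2). In females the mean was 2.94 ± 0.441 FPKM in controls, with 2.46, 3.33 and 3.03, and 3.57 ± 0.651 in libraries labelled knockout, with 4.04, 3.83 and 2.82. The female mean was 121% of control (exact permutation p = 0.3), where the smallest p that 3 against 3 libraries allow is 0.1. Stratified by sex over 400 arrangements the exact permutation p was 0.9, or 0.938 over the 64 that exchange labels only within same-numbered pairs. The averaged log2 change by limma was -0.01 (SE 0.0961, adjusted p = 0.975). Each Per1 value rested on 212 to 425 fragments. Transcript of Per1 was therefore not reduced past the test in the libraries labelled knockout of either sex, which goes against the genotype label, and directions below compare groups by their labels. The library names mark the allele as conditional, and the labels do not name the deleted part. A gene-level FPKM sums all exons, so a deletion that leaves most of the transcript would not be visible here.

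**Figure D1:**
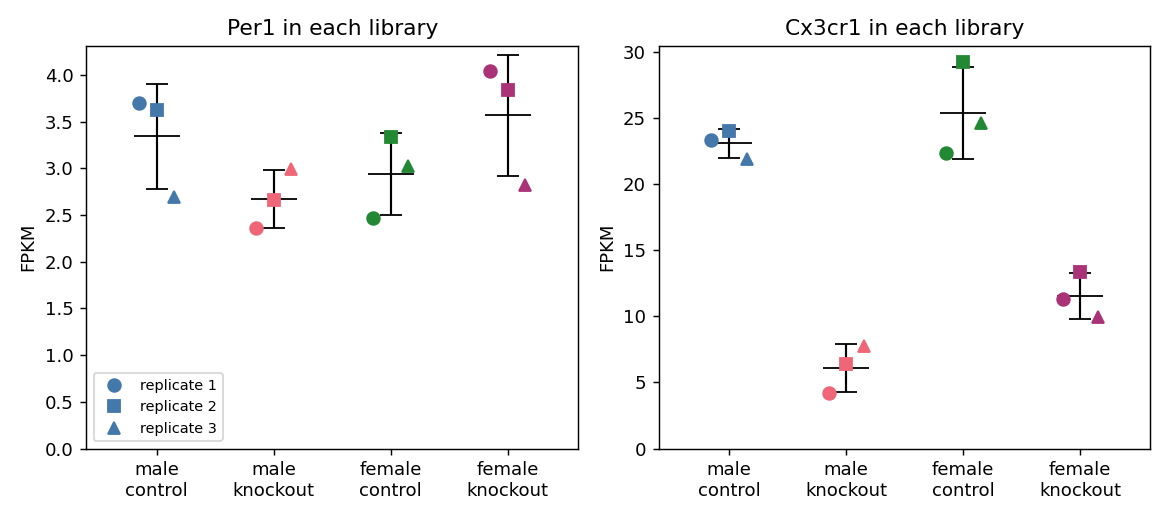
FPKM of Per1 (left) and Cx3cr1 (right) in each of the 12 libraries, by group, with symbols for the replicate number and black bars for the mean ± SD (n = 3). Per1 overlaps between libraries labelled knockout and control in both sexes, while Cx3cr1 lies at 4.19 to 7.77 FPKM in male and 9.93 to 13.4 in female libraries labelled knockout, below all controls.

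The sex labels were checked with Xist, the RNA that silences an X chromosome in female cells, and with Y-linked genes. Xist was at 40.5 to 61.4 FPKM in female libraries and at most 0.0035 FPKM, from 1 fragment, in male ones. Ddx3y was at 13.6 to 16.4 FPKM in male libraries and had 0 fragments in every female one. All 12 libraries matched their sex label.

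The first comparison asked what differed between male libraries labelled knockout and male controls. Cx3cr1 (ENSMUSG00000052336, chromosome 9, 119730682 to 119898945 on the minus strand in the table, build uncertain), the fractalkine receptor carried by monocytes, fell from 23.1 ± 1.08 to 6.12 ± 1.81 FPKM (SD, n = 3), or to 26.5% of control. Cell cycle genes were higher as a group, with 29 of 30 members positive and a median log2 change of 0.27 (limma camera adjusted p = 1.84e-11, and adjusted p = 0.496 with an estimated correlation). Lower as groups were the markers of monocytes and macrophages (25 of 27 negative, median -0.30), of MHC class II and dendritic cells (16 of 16, median -0.37) and the inhibitors of osteoclast formation (16 of 16, median -0.22), with limma adjusted p = 0.602, 0.602 and 0.496 with an estimated correlation. Pattern recognition and NF-kB genes (30 of 34 negative, median -0.22), glycolysis genes (16 of 17, median -0.17) and inflammatory mediators (20 of 27, median -0.13) were lower too, with limma adjusted p = 0.631, 0.751 and 0.809 with an estimated correlation.

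By limma, 0 of 12237 genes were higher and 1 was lower at an adjusted p under 0.05. At an unadjusted p under 0.05, 990 were higher and 800 lower, together 1790, where chance gives 612 over both directions. By voom on the rebuilt fragments 3 were higher and 10 lower. The gene called was Cx3cr1, with a log2 change of -1.79 (SE 0.174, limma adjusted p = 0.00856). In 1529 genes every library labelled knockout lay above every control and in 1338 below, together 23.4% of genes, where chance gives 10%. These chance values are means. Genes vary together, so a split of few libraries can lie far from them without a knockout effect. Other splits were not counted for these measures here, so the excess is not read as an effect of the label. The Cx3cr1 call ended without male control 1 (limma adjusted p = 0.0858), male control 2 (0.0698) or male knockout 2 (0.0588), and with the replicate number as a block within sex (0.0935). It also ended in the fit of the male libraries alone (limma adjusted p = 0.139), in the 8 libraries with the higher rRNA share (0.136) and in the 9 with a low interferon score (0.0509), with a range over all alternatives of 0.000587 to 0.139. The log2 change stayed between -1.96 and -1.58 in these fits.

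Among cell cycle genes, Mcm2 of the replicative helicase was at 10.3 ± 1.12 FPKM in male controls and 14.3 ± 0.644 in libraries labelled knockout (log2 change 0.43), and the licensing factor Cdc6 at 2.63 ± 0.331 and 3.93 ± 0.594 (0.44). Over all genes tested 0 members of this list passed limma at 0.05, with 17 at an unadjusted p under 0.05 and 10 higher when adjusted over the list alone. Of 27 monocyte and macrophage markers 1 passed over all genes, Cx3cr1, and 4 were lower adjusted over the list alone (camera of limma, adjusted p = 2.03e-05, and adjusted p = 0.602 with an estimated correlation). The list tests include Cx3cr1, and the other 26 members had a median log2 change of -0.2935. F13a1, the A chain of a coagulation factor made by macrophages, was at 19.9 ± 2.28 and 10.4 ± 2.52 FPKM (log2 change -0.89, limma adjusted p = 0.104).

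MHC class II and dendritic cell markers had a camera adjusted p of 2.53e-05 in limma, and an adjusted p of 0.602 with an estimated correlation. Of 16 members 3 were lower adjusted over the list alone and 0 over all genes. Ciita, the regulator of MHC class II genes, was at 2.51 ± 0.281 FPKM in male controls and 1.55 ± 0.234 in libraries labelled knockout, and H2-Aa, a class II chain, at 53.1 ± 10.9 and 33.3 ± 6.51. Inhibitors of osteoclast formation had an adjusted p of 7.24e-05 by limma's camera, and adjusted p = 0.496 with an estimated correlation, with 2 of 16 lower adjusted over the list alone. These were led by the repressor Hbp1 (12.96 ± 0.194 and 9.68 ± 0.0231 FPKM, log2 change -0.39) and the inhibitory receptor Pirb (71.8 ± 0.0387 and 56.3 ± 2.46, log2 change -0.35), each with a limma adjusted p of 0.104 over all genes.

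Pattern recognition and NF-kB genes had a camera adjusted p of 1.15e-04 in limma, and adjusted p = 0.631 with an estimated correlation. The lipopolysaccharide co-receptor Ly96 was at 8.69 ± 0.641 FPKM in male controls and 6.35 ± 0.429 in libraries labelled knockout, and Tlr2 at 14.4 ± 2.74 and 9.79 ± 2.03. Inflammatory mediators had a camera adjusted p of 0.0377 in limma, and adjusted p = 0.809 with an estimated correlation, with 1 of 27 lower adjusted over the list alone. The inflammasome sensor Nlrp3 was at 5.30 ± 0.305 and 3.24 ± 0.297 FPKM (log2 change -0.57), and the cytokine Il1b at 2.45 ± 0.742 and 0.724 ± 0.207 (log2 change -0.98). Glycolysis genes had a camera adjusted p of 0.00334 in limma, and adjusted p = 0.751 with an estimated correlation, and Aldoc, a glycolytic aldolase, was at 14.7 ± 1.93 and 10.2 ± 1.24 FPKM. The inflammatory list, with a mean log2 change of -0.2379, lost its call with the rRNA-share term at the same mean (limma camera adjusted p = 0.051) and with median ratio rescaling (0.0617, mean -0.2455). Its call also ended without male control 1, male control 3 or male knockout 1 (limma camera adjusted p = 0.0652, 0.331 and 0.15, means -0.2044, -0.1657 and -0.1635). In the 8 libraries with the higher rRNA share it ended too (0.6405, mean -0.09124). The glycolysis list lost its limma camera call without male control 2 (adjusted p = 0.0744, mean -0.1501 against -0.1774). With the replicate number as a block within sex complement (0.0294), immediate early genes (0.0303), V-ATPase and lysosome genes (0.0307) and coupling factors (0.0303) also passed limma's camera. With an estimated correlation, computed without the block, the first 3 had limma adjusted p = 0.751 each and coupling factors 0.496. With the rRNA-share term immediate early genes (limma camera adjusted p = 0.0229) and V-ATPase and lysosome genes (0.038) did, against adjusted p = 0.667 and 0.569 with an estimated correlation. Limma's fry with a direction passed 0 lists, and its test for change in either direction passed inhibitors, monocyte and macrophage markers and cell cycle (adjusted p = 0.0193 each) and the glucocorticoid response (0.0105). The monocyte and macrophage list includes Cx3cr1, and no fry result without it is given here.

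Osteoclast genes did not pass in males, with 17 of 27 members negative, a median log2 change of -0.03 and a limma camera adjusted p of 0.572. The collagenase Mmp9 was at 3783 ± 780 FPKM in male controls and 3185 ± 140 in libraries labelled knockout, and the transcription factor Mitf at 18.3 ± 2.21 and 22.0 ± 1.71. Clock genes had 11 of 16 members negative (limma camera adjusted p = 0.306), with Nfil3 at 5.67 ± 0.590 and 3.45 ± 0.486 FPKM and Rora at 2.23 ± 0.428 and 1.48 ± 0.036. Outside Cx3cr1, the protein-coding genes of lowest p in each direction, among those with separate groups and a mean of 2 FPKM or more in 1 of them, did not pass in limma. On the higher side these were Ifrd2 (8.58 ± 0.842 and 13.4 ± 0.684 FPKM), the amino acid transporter Slc7a5 (9.35 ± 0.552 and 14.8 ± 0.962), the spermidine synthase Srm (32.3 ± 1.56 and 51.4 ± 2.85), the transcription factor Tfap4 and the tRNA synthetase scaffold Aimp2, with limma adjusted p from 0.057 to 0.0852. On the lower side they were Calcoco1 (6.67 ± 0.363 and 4.69 ± 0.234 FPKM), the kinase Nuak1 (2.60 ± 0.410 and 1.198 ± 0.172), Klhl24 and Tcp11l2, with limma adjusted p from 0.057 to 0.0821.

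**Figure D2:**
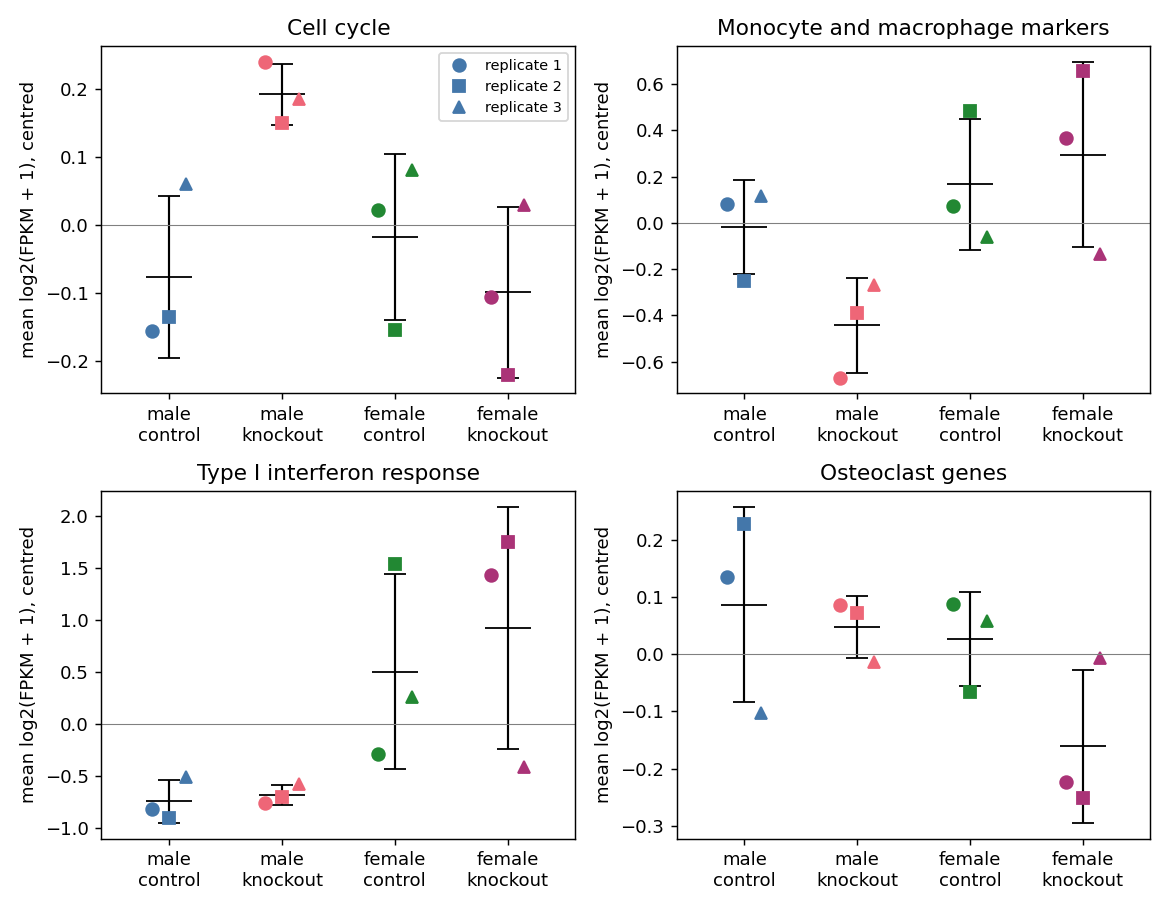
Score of 4 gene lists in each library, as the mean over the list's genes of log2(FPKM + 1) centred on the 12 libraries, by group, with symbols for the replicate number and black bars for the mean ± SD (n = 3). Cell cycle scores are 0.151 to 0.240 in male libraries labelled knockout against -0.155 to 0.0602 in male controls, and interferon scores are high in female control 2 (1.54), female knockout 1 (1.43) and female knockout 2 (1.74).

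The second comparison asked the same in females. Osteoclast genes were lower as a group in female libraries labelled knockout, with 25 of 27 members negative and a median log2 change of -0.17, with limma adjusted p = 0.937 with an estimated correlation. The proton pump subunit Atp6v0d2 was at 375 ± 72.2 FPKM in controls and 270 ± 52.3 in libraries labelled knockout, and Snx10 at 74.8 ± 5.49 and 61.4 ± 3.16. Nuclear genes of oxidative phosphorylation (25 of 30 negative, median -0.14) and V-ATPase and lysosome genes (20 of 28, median -0.13) were lower as well, both with limma adjusted p = 0.937 with an estimated correlation. Interferon response genes (39 of 39 positive, median 0.43), inflammatory mediators (24 of 27, median 0.27), MHC class II and dendritic cell markers (15 of 16, median 0.22), immediate early and heat shock genes (17 of 21, median 0.20) and pattern recognition genes (25 of 34, median 0.06) were higher as groups. These 5 lists too had limma adjusted p = 0.937 with an estimated correlation. Female control 2, female knockout 1 and female knockout 2 had far more interferon response transcript than the other 9 libraries, with scores of 1.54, 1.43 and 1.74 against -0.902 to 0.260. Cx3cr1 was at 25.4 ± 3.48 FPKM in controls and 11.5 ± 1.73 in libraries labelled knockout, 45.5% of control, which did not pass over all genes (log2 change -1.07, SE 0.174, limma adjusted p = 0.147).

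By limma 0 genes passed in females. At an unadjusted p under 0.05, 645 were higher and 745 lower, together 1390, where chance gives 612 over both directions. The lowest limma adjusted p was 0.141, of the small nucleolar RNA Gm25632, and voom called 0. In 781 genes all libraries labelled knockout lay above all controls and in 838 below, together 13.2%, against 10% by chance. The limit given for such chance values in males holds here too. The 3 lower lists had limma camera adjusted p of 3.59e-04 for osteoclast genes, 2.84e-04 for oxidative phosphorylation and 0.00675 for V-ATPase and lysosome, and adjusted p = 0.937 each with an estimated correlation. The 5 higher lists had 0.00675 for interferon, 0.00675 for inflammatory mediators, 0.0177 for MHC class II, 0.0279 for immediate early genes and 0.0347 for pattern recognition, and again 0.937 with an estimated correlation. In simulated libraries with no female change, whose genes were drawn independently, 2 lists passed limma's camera and 0 with an estimated correlation. In limma the 5 higher lists failed without any of female control 1, female control 3, female knockout 1 or female knockout 2, and with an rRNA-share term (adjusted p 0.193 to 0.909). Their mean log2 changes were 0.01213 to 0.1447 with the term, against 0.1261 to 0.4182 without it. Without 1 of these libraries the mean was 0.006872 to 0.2967 for interferon (against 0.4182) and 0.05636 to 0.2051 for inflammatory mediators (0.301). It was 0.02998 to 0.09194 for pattern recognition (0.1261), 0.1228 to 0.1815 for MHC class II (0.2262) and 0.1222 to 0.1712 for immediate early genes (0.2057). The term left the 3 lower lists, and 15 lists passed without female knockout 3. In the 9 libraries with a low interferon score, where female knockout 3 stood alone against 2 controls and was assumed to vary like the other groups, 1 list passed, and interferon genes were lower (mean log2 change -0.39). The 3 lower lists lost their limma camera calls there, with means of -0.08026 for osteoclast genes (against -0.1876), -0.04065 for oxidative phosphorylation (-0.1206) and -0.07078 for V-ATPase and lysosome (-0.1201). Quantile normalization also ended the limma camera calls of oxidative phosphorylation (adjusted p = 0.0637, mean -0.08802) and V-ATPase and lysosome (0.132, mean -0.09151). The latter call ended without female control 2 too (0.173, mean -0.0881).

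Osteoclast scores were lowest in female knockout 1 (-0.224) and female knockout 2 (-0.252), which belong to the 3 libraries of high interferon score, against -0.00711 in female knockout 3. Oxidative phosphorylation scores were likewise lowest in female knockout 1 (-0.1975) and 2 (-0.1472), while female knockout 3 (-0.03537) lay beside female control 2 (-0.02889). V-ATPase and lysosome scores were -0.08293, -0.0506 and -0.04078 in female knockouts 1, 2 and 3 and 0.008427 to 0.1259 in female controls. The complex I subunit Ndufa10 was at 35.0 ± 1.08 and 28.7 ± 2.93 FPKM, and the V-ATPase genes Atp6v1g1 at 322 ± 34.5 and 249 ± 11.2 and Atp6ap2 at 258 ± 31.8 and 198 ± 24.0. Of the interferon genes, Ifi27l2a was at 205 ± 174 and 483 ± 360 FPKM, so its groups overlapped widely. Il1b was at 2.08 ± 0.815 and 4.65 ± 3.16 FPKM, and the stress gene Ier3 at 7.07 ± 2.12 and 11.2 ± 3.14. None of the members of these 8 lists passed limma over all genes or adjusted over the list alone, with 11 oxidative phosphorylation, 8 V-ATPase and 7 osteoclast genes lower at an unadjusted p under 0.05.

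Glycolysis genes passed limma's camera in females with the replicate number as a block within sex (adjusted p = 0.0409, against 0.0723 without it), and had adjusted p = 0.937 with an estimated correlation, computed without the block. Clock genes did not pass as a list in females (10 of 16 positive, limma camera adjusted p = 0.152), although limma's fry for change in either direction gave an adjusted p of 0.0427, as it did for no other list in females. Adjusted over the list alone 3 of 16 were higher and over all genes none. These were Per3 (0.698 ± 0.0502 FPKM in controls and 1.44 ± 0.130 in libraries labelled knockout), the clock output factors Tef (3.94 ± 0.946 and 5.84 ± 0.189) and Dbp (2.51 ± 0.765 and 4.70 ± 0.663), with limma adjusted p over all genes of 0.281, 0.366 and 0.366. Among protein-coding genes outside the lists with separate groups and a mean of 2 FPKM or more in 1 of them, those of lowest p in each direction were H60b, a ligand of natural killer cell receptors (0.844 ± 0.182 and 2.21 ± 0.472 FPKM), Mapk8ip3, Kctd17, Vasn and Ppox on the higher side and Ccdc130, Sh3bgrl2, Ranbp9 and Akr1c13 on the lower, with limma adjusted p from 0.147 to 0.285.

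The third comparison averaged both sexes. Cx3cr1 was lower in each of the 6 libraries labelled knockout than in every control of its sex. Its averaged log2 change was -1.43 (SE 0.123, limma adjusted p = 0.00251). Its exact permutation p was 0.005 stratified by sex, or 0.0312 with labels exchanged only within same-numbered pairs, the smallest these allow. The gene was picked on the same libraries and these permutation p are not adjusted over genes, so they are no independent evidence. In both sexes, 64 genes lay above every control of the same sex in all libraries labelled knockout, and 87 lay below. Together these were 1.23% of genes, where chance gives 0.5% if each sex has 10%. The sexes had 23.4% and 13.2%, and independent lists of those sizes would share more than 0.5%. The 1.23% is therefore not read as a response shared by the sexes. Cell cycle genes (24 of 30 positive, median 0.10) and interferon response genes (39 of 39, median 0.22) were higher as groups, with limma adjusted p = 0.842 and 0.968 with an estimated correlation. The interferon score was carried by female control 2, female knockout 1 and female knockout 2 (1.54, 1.43 and 1.74 against -0.902 to 0.260 elsewhere). V-ATPase and lysosome genes (26 of 28 negative, median -0.10), osteoclast genes (23 of 27, median -0.08), oxidative phosphorylation genes (22 of 30, median -0.07), monocyte and macrophage markers (18 of 27, median -0.13) and protein genes of the mitochondrial genome (9 of 13, median -0.14) were lower, each with limma adjusted p = 0.842 with an estimated correlation. Tfap4 (4.99 ± 0.304 and 7.28 ± 0.332 FPKM in males, 4.09 ± 0.378 and 4.82 ± 0.382 in females) and the metalloreductase Steap4 (34.6 ± 3.92 and 25.4 ± 2.81, 34.9 ± 2.00 and 26.2 ± 1.46) were among the protein-coding genes of lowest p that did not pass and had separate groups in both sexes, both at a limma adjusted p of 0.172. The osteoclast protease Ctsk, cathepsin K, was at 6843 ± 1130 and 6244 ± 815 FPKM in males and 6446 ± 1150 and 4808 ± 768 in females (averaged log2 change -0.27, limma adjusted p = 0.479).

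Limma called 0 genes higher and 1 lower, Cx3cr1, with 610 higher and 664 lower at an unadjusted p under 0.05, and voom called 0 and 1. The Cx3cr1 call was kept without each of the 12 libraries in turn and ended in the 8 libraries with the higher rRNA share (limma adjusted p = 0.0646) and in the 9 with a low interferon score (0.0785), with a range over all alternatives of 0.000105 to 0.0785. The log2 change there was -1.445 and -1.475, no smaller than with all libraries, so these losses go with fewer libraries. The limma camera adjusted p was 7.39e-05 for cell cycle, 2.01e-04 for V-ATPase and lysosome, 0.00149 for osteoclast genes, 0.0043 for oxidative phosphorylation, 0.00547 for monocyte and macrophage markers, 0.0214 for interferon and 0.0456 for the mitochondrial genome, against adjusted p = 0.842 to 0.968 with an estimated correlation. The interferon call ended in limma with the rRNA-share term (type I interferon response, adjusted p = 0.493), and its direction turned without the 3 libraries (mean log2 change -0.1662) and in the 8 libraries with the higher rRNA share (-0.2006). The same term brought inhibitors of osteoclast formation (limma camera adjusted p = 0.0045), pattern recognition (0.0146), coupling factors (0.0173) and MHC class II and dendritic cell markers (0.0319) past 0.05, all lower. With an estimated correlation and the term these had limma adjusted p = 0.405, 0.82, 0.289 and 0.844. Limma's fry for change in either direction passed clock genes and monocyte and macrophage markers (adjusted p = 0.0277 each). The tests of the monocyte and macrophage list include Cx3cr1, and no result without it is given here. The other 26 members had a median averaged log2 change of -0.124. The mitochondrial genome list lost its limma camera call with the replicate number as a block within sex (adjusted p = 0.0534) at the same mean log2 change of -0.09984, and in 10 other alternatives (means -0.1202 to -0.03521). Without 1 library the limma camera call also ended for monocyte and macrophage markers in 3 of 12 fits (means -0.09141 to -0.03997, against -0.1479). It ended for oxidative phosphorylation in 2 (-0.04014 and -0.02808, against -0.05784) and for interferon in 6 (0.03446 to 0.2147, against 0.2401). Quantile normalization ended the oxidative phosphorylation call as well (limma camera adjusted p = 0.202, mean -0.0401). Without female knockout 1 only 4 lists passed. In the 9 libraries with a low interferon score the averaged osteoclast call ended (limma camera adjusted p = 0.177, mean -0.05951 against -0.1132). Of the inhibitors of osteoclast formation 2 of 16, Hbp1 and Pirb, were lower adjusted over the list alone and none over all genes (limma camera adjusted p = 0.0578 for the list).

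Markers of other bone marrow cell types did not pass in the averaged contrast. Limma's camera gave adjusted p of 0.615 for neutrophils (20 genes), 0.504 for mast cells, basophils and eosinophils (11), 0.961 for stromal cells (5), 0.458 for lymphocytes (11), 0.615 for erythroid cells (9) and 0.931 for endothelium (4). The remaining lists gave 0.358 for complement, 0.123 for coupling factors made by osteoclasts, 0.305 for the glucocorticoid response, 0.466 for cholesterol synthesis, 0.615 for ribosomal proteins, 0.732 for clock genes, 0.931 for inflammatory mediators, 0.285 for pattern recognition, 0.166 for MHC class II, 0.995 for immediate early genes and 0.466 for glycolysis.

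The fourth comparison tested whether the difference between libraries labelled knockout and control itself differed between the sexes. Limma called 0 genes. At an unadjusted p under 0.05, 916 were more positive in females and 1159 more positive in males, together 2075, where chance gives 612 over both directions. This chance value has the limit given in the male comparison. The lowest limma adjusted p was 0.18, and voom called 0. The genes of lowest p included the long noncoding RNA Neat1 (22.4 ± 0.355 and 17.5 ± 1.75 FPKM in males, 17.5 ± 1.71 and 24.4 ± 2.43 in females) and the mediator subunit Med19 (8.34 ± 0.474 and 10.6 ± 0.466, 9.90 ± 0.110 and 8.56 ± 0.135). The ribosome assembly factors Mrto4 (11.2 ± 0.832 and 15.4 ± 0.540, 11.3 ± 0.879 and 9.90 ± 0.520) and Brix1 were also among them. Cx3cr1 was lower in both sexes, with a difference of 0.71 on the log2 scale (SE 0.246, limma adjusted p = 0.227).

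By limma's camera 7 lists were more positive in females and 2 more positive in males, all 9 with adjusted p = 0.610 to 0.745 with an estimated correlation. On the female side were MHC class II and dendritic cell markers (median difference 0.61, adjusted p = 9.69e-06), pattern recognition (0.27, 5.93e-05), inhibitors of osteoclast formation (0.28, 3.29e-04), monocyte and macrophage markers (0.48, 3.65e-04), inflammatory mediators (0.60, 9.28e-04), glycolysis (0.24, 9.75e-04), and immediate early genes (0.37, 0.00422). On the male side were cell cycle (limma adjusted p = 4.08e-08, median -0.37) and oxidative phosphorylation (0.0096, median -0.13). The oxidative phosphorylation call ended with quantile normalization (limma camera adjusted p = 0.295, mean -0.09584 against -0.1255). It also ended without male control 3 (0.174, mean -0.07878) or female knockout 1 (0.0821, mean -0.09011). Of cell cycle genes 8 differed adjusted over the list alone, and 1 inflammatory and 1 immediate early gene did, while none differed over all genes. In an exact permutation of genotype labels within sex on list scores the lowest adjusted p over the 25 lists was 0.125, or 0.13 with labels exchanged only within same-numbered pairs. The 0.125 was that of clock genes, which are not among the 9 lists, and the lowest of the 9 was 0.25. Freely within sex the smallest permutation p possible is 0.005, which clock genes had, so no list could pass alone after adjustment over 25 lists. Within pairs the smallest p possible is 0.0312, so a pass after adjustment would need most of the 25 lists at that value. With the replicate number as a block within sex osteoclast genes (limma camera adjusted p = 0.0256) and complement (0.0369) differed as well, and had adjusted p = 0.798 and 0.788 with an estimated correlation, computed without the block. Osteoclast genes also differed by limma's camera with the rRNA-share term (adjusted p = 0.0125, and adjusted p = 0.806 with an estimated correlation). These differences share their libraries with the 3 of high interferon score, and in the 8 libraries with the higher rRNA share the inflammatory difference turned negative (mean -0.09). Of the 9 limma camera calls 6 ended in those 8 libraries, and 4 in the 9 with a low interferon score, all with smaller mean differences.

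Across 12237 genes, the male and female log2 changes had a Pearson correlation of -0.18 (jackknife SE 0.211 over libraries), and genes are not independent replicates. At an unadjusted p under 0.05 in both sexes 41 genes were higher in both and 41 lower in both, where independent lists give 52.2 and 48.7, and 113 were opposite, where they give 102. With the rRNA-share term the correlation was -0.02, with 53 genes higher in both, 78 lower in both and 59 opposite, where independent lists give 43.4, 36.2 and 80.3. The excess of opposite genes thus turned into an excess of genes of the same sign. With the replicate number as a block within sex 37 were higher in both, 49 lower in both and 215 opposite, where they give 64.6, 71 and 138. The range of the correlation without each library in turn was -0.247 to -0.039.

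**Figure D3:**
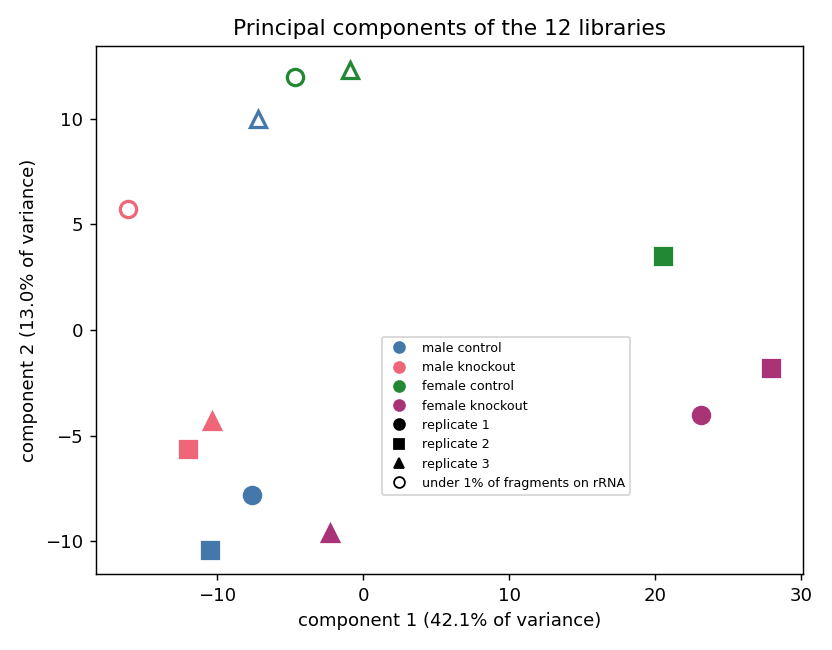
First and second principal components of log2(FPKM + 1) of the 1000 most variable genes in the 12 libraries, coloured by group, with symbols for the replicate number and open symbols for the 4 libraries with under 1% of fragments on rRNA genes. Component 1 (42.1% of variance) sets female control 2, female knockout 1 and female knockout 2 (20.6 to 28.0) apart from the other 9 libraries (-16.1 to -0.885), and the open symbols have the highest values on component 2 (12.98%).

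The last comparison, of female with male controls, gave the sex difference without the knockout. Xist was higher and the Y-linked genes Ddx3y, Eif2s3y, Uty, Kdm5d and Gm29650 were lower in female controls, and Gdf3, a growth factor of the TGF-beta family, was at 12.5 ± 3.598 FPKM in female and 3.46 ± 1.18 in male controls (log2 change 1.60, limma adjusted p = 0.0415). The Gdf3 call ended with the replicate number as a block (limma adjusted p = 0.128), with the rRNA-share term (0.129) and without any 1 of the 12 libraries except female control 3 (0.0756 to 0.168, and 0.00972 without that one). Its log2 change stayed at 1.602 with the block and with the term, and at 1.357 to 1.84 without 1 library. Its limma adjusted p had a range of 0.00972 to 0.646 over all alternatives. In the control libraries alone Kdm5d and Gm29650 (limma adjusted p = 0.0665 each) also missed 0.05. Limma called 2 genes higher and 5 lower, with 682 at an unadjusted p under 0.05 where chance gives 612, and voom called 4 and 5. The genes known to escape X inactivation Kdm6a (4.45 ± 0.401 FPKM in male and 6.76 ± 0.396 in female controls) and Eif2s3x (29.6 ± 1.66 and 48.0 ± 6.34) had limma adjusted p of 0.0699 and 0.117.

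The libraries differed in a way their labels do not give. The share of fragments on rRNA genes was 0.526% to 0.632% in male control 3, male knockout 1, female control 1 and female control 3, and 1.24% to 1.57% in the other 8. In males the lower share fell on 1 library of each group. In females it fell on 2 of 3 controls and 0 of 3 libraries labelled knockout, so it is largely confounded with the label. A term for this division, added after seeing the data, passed limma in 868 genes, 367 higher and 501 lower in the libraries with the lower share. With the term in the fit, limma called 181 genes higher and 79 lower in males, 0 in females, where 818 passed an unadjusted p under 0.05, and 1 in the averaged contrast. Of the 260 male calls 1 was left with the replicate number as a block beside the term, and between 1 and 62 genes passed when 1 male library was left out (1, 62 and 19 without male controls 1, 2 and 3, and 2, 1 and 2 without male knockouts 1, 2 and 3). All 260 kept their sign there, and their median log2 change in that direction was 0.3704 to 0.4145, against 0.4001 with all libraries. These genes were picked on all libraries, so their sign and size in subsets of the same libraries were largely fixed beforehand. With the term and all libraries, Cx3cr1 had limma log2 changes of -1.79 in males (adjusted p = 0.0012), -1.31 in females (0.074) and -1.55 averaged (3.79e-04).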

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

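All tests weighed in this part on Cx3cr1, and those of the interferon pattern on the rRNA share and the genotype, were chosen only after the result was seen. The difference between the sexes passed limma's camera at 0.05 in 9 lists, none of which passed with an estimated correlation (lowest adjusted p = 0.610), given here as median differences in log2 change, female minus male, with directions resting on labels that Per1 transcript did not follow. It was 0.279 for inhibitors of osteoclast formation and 0.2391 for glycolysis. It was 0.5986 for inflammatory mediators, 0.2679 for pattern recognition and 0.3702 for immediate early genes. It was 0.4765 for monocyte and macrophage markers and 0.6111 for MHC class II and dendritic cell markers. It was -0.3682 for cell cycle and -0.1271 for oxidative phosphorylation.

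Cx3cr1 was lower in every library labelled knockout, at 26.5% of control in males and 45.45% in females. A smaller share of monocytes and macrophages in these cultures was argued against as the whole cause, since the other 26 members of the list had a median averaged log2 change of -0.124 (SD 0.2045) against -1.43 for Cx3cr1. That average pools opposite signs. The median was -0.2935 (SD 0.3628) in males, against -1.789 for Cx3cr1, and 0.1125 (SD 0.2812) in females, against -1.074. A smaller share as part of the male fall is not excluded. The median covers the list as a whole, so a loss of only some of these cells, with their own markers, was not tested. The library set seen in the rRNA share was argued against as the whole cause too, with an averaged change of -1.548 with a term for it. That set takes 1 library of each male group, so the male change of -1.789 could not move with the term. Only the female change could, and it was -1.306 with the term, no smaller than without it. With the term the female change did not pass over all genes (limma adjusted p = 0.074). A Cre allele inserted in Cx3cr1, a common myeloid driver that removes 1 copy of the gene, could give a level near 0.5 of control, and the 45.45% of females would fit that while the 26.5% of males lies below it. The labels name no driver, so this stays open, and a genotype of the mice would settle it.

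Interferon response genes were high in female control 2, female knockout 1 and female knockout 2. These 3 were picked after their high scores were seen, so gaps above 0 were known beforehand. The library set seen in the rRNA share was argued against as the only cause, since these 3 lie 1.84 above the other 5 libraries of their set, more than the range of 1.162 over the 9 others. The genotype was argued against as the only cause, since female control 2 lay 1.951 above female knockout 3. A partial role of the genotype stays open, since that compares 1 library with 1. Cells of another bone marrow type could be present, as 1 of 5 marker lists, that of lymphocytes, lay above all 9 other libraries, by 0.1155 against 1.17 for interferon. That test, chosen before, leaves it open, and so do lists outside its 5 that lay above as well, endothelial markers by 0.4115, MHC class II and dendritic cell markers by 0.2682 and monocyte and macrophage markers by 0.2484.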

How the results depend on the processing

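Alternative settings were run on each contrast they apply to, which leaves out the block within sex for female against male controls and a fit of the compared groups alone for the averaged contrast and the difference between the sexes, and the correlation between the sexes was run in 16 of them. The cause was not tested where a value moved, unless fewer libraries or genes explain it. With 3 libraries per group and 15366600 to 24346288 fragments each, small changes could be found only in part, and genes near the floor of 0.119 to 0.188 FPKM were out of reach. In simulated libraries 1.5-fold changes were recovered in 44.8% of genes in males, 49.3% in females, 62.7% averaged and 19.4% for the difference between the sexes. The replicate number as a block changed no gene call of the knockout contrasts, ended that of Gdf3 between female and male controls (limma adjusted p = 0.128), and brought immediate early genes (limma camera adjusted p = 0.0442) and V-ATPase and lysosome genes (0.0448) past the threshold in males. As a block within sex it left 0 male genes and 11 male lists, ended the averaged call of the mitochondrial genome (0.0534) and brought 1 female list and 2 lists of the difference between the sexes past the threshold. With the rRNA-share term in the fit, the block took male genes from 260 to 1 and ended the call of Gm29650 between female and male controls (0.0732). In the fits without that term it changed no other call. The library weights (0.286 to 9.11) gave 1182 male genes, and also 1323 in a male split with exchanged labels, so their counts are not read as knockout effects. In the 8 libraries with the higher rRNA share female control 2 stands alone, and in the 9 with a low interferon score female knockout 3 does, and each is assumed to vary like the others.

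Genes past the threshold in males numbered 1 in the fit used and 4 on log2(FPKM + 0.1), 3 on log2(FPKM + 0.5), 2 with no filter on low values, 7 with FPKM of 5 or more in at least 3 libraries and 6 with median ratio rescaling. They numbered 0 with the replicate block within sex, 1182 with library weights, 13 with voom on rebuilt fragments, 27 at an adjusted p under 0.1 and 260 with the rRNA-share term. They numbered 0 in each of the 8 libraries, the 9 libraries and the male libraries alone. Without 1 library they ranged from 0 (without male control 1, male control 2 or male knockout 2) to 64 (without male control 3).

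In females they numbered 0, and 75 with no filter on low values, 3 with no variance trend, 4890 with library weights and 2 in the 9 libraries, and 0 to 1 without 1 library (1 without female knockout 1). In the averaged contrast they numbered 1, and 13 with no filter, 2068 with library weights, 0 in the 8 libraries, 0 in the 9 libraries, and 1 to 1 without 1 library. In the difference between the sexes they numbered 0, and 1 on log2(FPKM + 0.1), 16 with no filter, 3903 with library weights, 1 in the 9 libraries, and 0 to 1 without 1 library (1 without female knockout 1). Between female and male controls they numbered 7, and 4 with FPKM of 5 or more, 4 in the 8 libraries, 4 in the control libraries alone, and 6 to 8 without 1 library (Gdf3 lost in 11 of these 12 fits).

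Gene lists past the threshold in males numbered 7, and 0 with camera with estimated correlation, 0 with directional fry, 11 with the replicate block within sex, 12 in the 8 libraries, 11 in the 9 libraries, and 6 to 11 without 1 library (11 without male control 2). In females they numbered 8, and 0 with camera with estimated correlation, 0 with directional fry, 3 with the rRNA-share term, 1 in the 9 libraries, and 3 (without female knockout 1) to 15 (without female knockout 3) without 1 library. In the averaged contrast they numbered 7, and 0 with camera with estimated correlation, 0 with directional fry, 0 with exact permutation of library scores, 0 with this permutation within pairs, 11 in the 8 libraries, 13 in the 9 libraries, and 4 (without female knockout 1) to 9 without 1 library. In the difference between the sexes they numbered 9, and 0 with camera with estimated correlation, 0 with directional fry, 0 with exact permutation of library scores, 0 with this permutation within pairs, and 8 to 13 without 1 library. The permutation within pairs allows no p under 0.0312, so its count of 0 in these last 2 contrasts was nearly fixed by the design. The free permutation allows no p under 0.005, so no list could pass alone there after adjustment, and its count of 0 is weak evidence of no change. Fry for change in either direction passed 4 lists in males, 1 in females, 2 in the averaged contrast and 0 in the difference between the sexes.

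Directions turned in a few cases. The averaged Per1 change turned from -0.0146 to 0.001251 when rescaled without mitochondrial and top 20 genes. Without 1 library Per1 ranged from -0.35 to -0.18 in males, 0.12 to 0.33 in females and -0.07087 to 0.04675 averaged, and was above 0 without male control 1 (0.0163), male control 2 (0.0107), male knockout 1 (0.0160), female control 2 (0.0211) or female knockout 3 (0.04675). Lilrb4a in females was -0.03415 in only the 9 libraries with a low interferon score. In only the 8 libraries with the higher rRNA share the mean log2 change in females was -0.1798 for inflammatory cytokines, chemokines and mediators, -0.1416 for pattern recognition and NF-kB pathway, -0.6192 for type I interferon response, -0.05139 for MHC class II and dendritic cell markers and -0.03039 for immediate early and heat shock genes. There it was -0.2006 for interferon averaged and -0.08852 for the inflammatory difference between the sexes. In the 9 libraries it was -0.1398 for inflammatory mediators in females, and for interferon -0.3945 in females and -0.1662 averaged. The correlation of male and female changes ranged from -0.247 to -0.039 without 1 library and was -0.01746 with the rRNA-share term.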

Other observations

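The tests of ribosome biogenesis and of the library set in this part were chosen only after the male genes were seen, except the divisions and the libraries left out, which were chosen before. With a term for the rRNA share, limma called 181 genes higher and 79 lower in male libraries labelled knockout. The term marks 1 library of each male group, so male log2 changes were the same without it and no sign could differ. Of the 260 genes, 257 had an unadjusted p under 0.05 by limma without the term. Higher were factors of nucleolus and ribosome assembly, Nolc1 (19.57 and 31.09 FPKM, limma adjusted p = 0.0277), Mybbp1a (32.51 and 47.92, 0.0271) and Dkc1 (14.58 and 21.38, 0.0283), and the cell cycle transcription factor Mybl2 (7.628 and 11.94, 0.0277). Of cell cycle genes 8 of 30 passed, Mcm2 to Mcm7, Ccne1 and Cdc6. Lower, beside Cx3cr1, were the adhesion receptor Adgre4 (9.839 and 3.531 FPKM, limma adjusted p = 0.0277), the stress gene Ndrg1 (10.22 and 5.498, 0.0277), Selenbp1 (11.2 and 6.04, 0.0386) and Gpr18 (2.383 and 0.9512, 0.0386). With the term in the fit limma called 0 genes for the difference between the sexes. With the replicate number as a block beside the term, only the male call of Cx3cr1 was left (limma adjusted p = 0.0127).

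A list of 60 ribosome biogenesis genes, written after these genes were seen and so not independent of them, had 59 positive in males with a median log2 change of 0.37. Its limma camera p was 1.12e-28, and p = 0.0414 with an estimated correlation, both unadjusted. Scores were 0.353, 0.243 and 0.190 in male libraries labelled knockout and -0.177, -0.130 and 0.0628 in male controls. In females 50 of 60 were negative with a median of -0.09 (limma camera p = 0.00143, and p = 0.507 with an estimated correlation).

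A hypothesis is that ribosome biogenesis genes are higher as a group in male libraries labelled knockout. The scores of the male groups were apart by 0.1267, but the list was written after its top genes were seen and scored on the same libraries, so this gap tests nothing. The hypothesis stays untested here, and new male libraries would test it.

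The larger number of male genes once the rRNA-share term is added was weighed against chance and single libraries. Any term of the same shape was argued against, since only 1 of 27 divisions that take 1 library of each male group and 2 female controls, the real one, gave as many as 260 genes, and the highest other gave 25. Leaving out 1 male library cannot tell whether an outlying one carries it, since the number with the term fell whichever was left out, to 1, 62 and 19 without male controls 1, 2 and 3 and 2, 1 and 2 without male libraries labelled knockout 1, 2 and 3, as a smaller design would also give. The 260 genes all kept their sign there, with a median log2 change in that direction of 0.3704 to 0.4145 against 0.4001 with all libraries. They were picked on all libraries, so this was largely fixed beforehand and is no sign that the calls hold. With the replicate number as a block beside the term 1 gene passed, so the count stays open.

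Labels were also exchanged among the libraries compared, freely within a contrast's libraries and so across the batches that pair them. The splits that part every same-numbered pair, as the real one does, are given beside them. In males 3 of 10 splits gave as many genes as the real 1 (highest other 1), and 6 of 10 as many lists as the real 7 (highest other 15), and among the 4 that part every pair the highest others were 1 and 14. In females 7 of 10 gave as many lists as the real 8 (highest other 16, or 10 among the 4 that part every pair). Against a real count of 0 genes all 10 female splits and all 100 of the difference between the sexes count as large by construction, so these say nothing of chance. The highest other female split gave 1980 genes and sets the 3 libraries of high interferon score against the rest, parting fewer pairs, while those that part every pair gave at most 0, so these libraries have a structure that their labels do not give. In the averaged contrast 15 of 100 gave as many genes as the real 1 (highest other 2408) and 63 as many lists as the real 7 (highest other 19), so chance cannot be excluded. Of all 32 possible splits that part every pair, counted apart from the 100 drawn at random, 2 gave as many genes (highest other 1) and 18 as many lists (highest other 18), which leaves that reading as it was. In the difference between the sexes 54 of 100 gave as many lists as the real 9 (highest other 19), and 11 of the 32 that part every pair (highest other 18), where chance cannot be excluded either, and the highest other for genes was 448. Between female and male controls 2 of 10 gave as many genes as the real 7, and the highest other, with 140, follows the rRNA share, while the others that part every pair gave 0. With 10 or 4 splits no share under 0.05 can be reached.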
